A study of Mus musculus with 90 samples.

How the data were processed

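Liver RNA from 90 mice of 15 inbred strains was measured on 2-colour Agilent whole-genome expression arrays, 1 array per mouse. The mice had received a high-fat diet (HFD) or the same kind of diet containing ethanol (EtOH) by gastric tube for 28 days, and each of the 30 combinations of strain and diet held 3 mice. Per the labels, the RNA of the mouse carried Cy5 and a common mouse liver reference carried Cy3 on every array, with no dye swap, so a higher log ratio means more RNA in the mouse than in the reference. A dye effect that is the same on every array cancels in a difference between groups. The strain was taken from the sample titles, which give 3 mice per strain and diet. A second strain entry in the labels differed from the title in 77 of 90 samples and matched it in 13, and a grouping by that entry was run as an alternative.

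The deposited scanner files hold 45018 spots per array, among them 1639 control spots, and 41174 probes. Per the file headers, spots were quantified with Feature Extraction 9.5.1.1, and the files give the mean signal and the median local background of each channel as intensity on a linear scale. Per the file headers, the same files also hold a log10 ratio of Cy5 over Cy3 after Agilent's background subtraction, spatial detrending, and linear and lowess dye normalization. The deposited flags for spots above background, saturated spots and outlier spots were used as given. The series' design text states that batches were adjusted with ComBat by the submitters, but the scanner values used here are from before that step. The genome build was not given in the sources used here, so no coordinates are printed.

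The mean signals were corrected for the median local background with normexp and an offset of 50, and each array was normalized by loess within the array, with control spots at weight 0. The median net Cy5 intensity ranged from 38.2 to 192.5 between arrays (median 97.3) and the median net Cy3 intensity from 83.7 to 151. Control spots and outlier spots (0.410% of spots) were then left out and spots of the same probe were averaged. Between 50.4% and 63.9% of probes on an array lay well above background in the Cy5 channel. A probe was kept where it lay well above background on all 3 arrays of at least 1 of the 30 groups, which left 25620 probes. For each gene the probe with the highest mean brightness was used, giving 17572 genes. Of the 8012 further probes of these genes, 4115 belonged to a gene called in the mean over strains; 3573 of them had the same sign as the chosen probe, 540 the opposite sign, and 109 had the opposite sign and passed the threshold themselves. Names came from a RefSeq gene table of assembly GRCm38.p6, by accession for 11710 genes, by symbol for 1793 and by synonym for 838, and 3231 kept the name in the file.

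Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; statmod 1.5.0, data.table version 1.17.8), with a mean for each of the 30 groups and a term for each of 5 batches. Each batch held 9 EtOH and 9 HFD arrays, and each group of 3 mice lay in 3 of the 5 batches. The EtOH and HFD arrays of a batch came mostly from different strains, so a value within a single batch mixes strain with diet. Likewise, the diets of a strain shared only a single batch. A change within a strain thus rests on batch terms that assume the same shift in every strain. The fit had 56 residual degrees of freedom and 3.26 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The comparisons were EtOH against HFD as the unweighted mean of the 15 strain effects, EtOH against HFD within each strain, the interaction of strain and diet, differences among strains on HFD, and 2 pairs of related substrains on HFD. Errors on fitted changes are standard errors (SE) of this fit, and errors on group means are standard deviations (SD) over mice. The SE of a gene pools its spread over all 30 groups, so it can understate the error in a group that varied more.

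The comparisons, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The rule took, for the mean over strains, the 12 largest rises and 12 largest falls among called genes with a symbol that had the same sign in at least 12 strains and lay above background on at least 23 of the 45 arrays of each diet. It also took the largest rise and fall in each strain, among called genes with a symbol above background on all 6 arrays. Added were the 10 interaction genes and 10 strain-difference genes of smallest p with a symbol and above background on at least 45 arrays. So were the 5 largest changes each way in each substrain pair, among called genes with a symbol above background on all arrays of at least 1 group. Last came the 5 genes with a symbol called each way in most strains, ties going to the larger mean change, and up to 4 members per list by smallest p. Other genes named in the text were chosen after their values were seen, which covers members named because a list had few calls in a direction and the calls named in AKR/J.

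The 34 lists covered ethanol oxidation, methionine and one-carbon metabolism, the unfolded protein response, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, lipid droplets and lipid uptake, bile acids, xenobiotic P450 enzymes, glutathione and Nrf2 targets, inflammatory signalling, the acute phase, the interferon response, the cell cycle, damage and early stress genes, glucose metabolism, the circadian clock, male-typical and female-typical liver genes, iron and heme, oxidative phosphorylation, and markers of extracellular matrix and stellate cells, hepatocytes, Kupffer cells and macrophages, neutrophils, T and NK cells, B and plasma cells, MHC class II, sinusoidal endothelium, cholangiocytes, erythroid cells, pancreatic acinar cells, adipocytes and skeletal muscle. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the members move one way on balance and does not compare them with other genes. Some genes stand on more than 1 list: Cyp2b9, Cyp2b13, Cyp3a41a and Cyp3a44 on the P450 and female-typical lists, Cyp2d9 on the P450 and male-typical lists, Slco1a1 and Cyp7b1 on the bile acid and male-typical lists, and Hamp on the acute-phase and iron lists.

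Tested on simulated data with the real layout, the fit over 15 strains recovered 100% of genes changed by 1.5, 2 or 4 fold, with 8 false calls among 17572 genes. For AKR/J alone it recovered 49.3%, 77.6% and 100% of genes at those sizes, with 5 false calls. The simulated noise was independent between genes, equal on all arrays and without batch effects. The real arrays were less even, with estimated array weights from 0.107 to 5.27, and another split of the real AKR/J mice called 261 genes. The simulated rates therefore do not carry over to the real data. The alternatives were no background correction, Agilent's own log ratio, Aquantile normalization, the Cy5 channel alone, no filter on dim probes, a filter requiring signal on all arrays, no batch term, ComBat, batch or slide as a random block, array weights (whose REML fit warned that it stopped before its tolerance was reached), the mean of all probes, the other strain entry, an additive model, each batch alone, fewer strains, and leaving out each mouse. Leaving out arrays of low weight was added after seeing the data. Further arrays of a common RNA, 2 per batch, were used to gauge repeat error and were correlated with the groups of mice, but entered no fit.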

Results

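Livers of 90 mice from 15 inbred strains were compared after 28 days of feeding by gastric tube with a high-fat diet (HFD) or a high-fat diet containing ethanol (EtOH), a way of feeding that sets the intake of each animal. Each strain gave 3 mice per diet, so each diet held 45 mice, and the labels name each replicate as a separate animal. The strains included the substrain pairs C57BL/6J with C57BL/10J and BALB/cJ with BALB/cByJ, and the 3 wild-derived strains MOLF/EiJ, PWD/PhJ and WSB/EiJ. Every liver was hybridised against the same kind of reference liver RNA on 1 array, and values are log2 ratios to that reference. The arrays lay on 25 slides in 5 batches of 18 arrays. Between 50.4% and 63.9% of probes lay well above background in the liver channel. The 10 arrays of a repeated common RNA had a median SD of 0.104 within a batch and 0.14 over all 10.

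Genes known to differ between these strains were read first as a check of the strain names. Nnt, the mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J, had its lowest mean in C57BL/6J (log2 ratio -1.36 ± 0.22, SD, n = 6) and its next lowest in PWD/PhJ (-0.72). Acads, the short-chain acyl-CoA dehydrogenase lost in BALB/cByJ, was lowest in BALB/cByJ (-2.04 ± 0.14, SD, n = 6) and next lowest in PWD/PhJ (-0.73). Afp, the fetal liver protein, and H19 and Gpc3 had their highest means in BALB/cJ (1.24, 0.78 and 1.05), the strain with a mutation in their repressor Zhx2, with the next at 0.71 in C57BL/6J, 0.76 in C57BL/10J and 0.91 in WSB/EiJ. Zhx2 itself lay above background on 0 of 6 arrays there. Glo1, set as high in AKR/J and DBA/2J, stood at 1.06 and 0.94 there but was highest in BALB/cByJ (1.49). The female-specific transcript Xist was well above background on at most 11 arrays with any of its 4 probes, and the Y-linked gene Ddx3y on all 90.

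The comparison of EtOH with HFD over 15 strains takes the mean of the 15 strain changes, and 863 of the genes it called also differed between strains in their change. The largest rise was that of Abcc4, an ATP-driven efflux transporter of organic anions, by 2.85 ± 0.14 (SE) on the log2 scale, or 7.20-fold, from 0.03 ± 1.08 on HFD to 2.88 ± 1.08 on EtOH (SD, n = 45 each). Cbr3, a carbonyl reductase, rose by 2.27 ± 0.14 and the cytochrome P450 genes Cyp2a4 and Cyp2a5 by 2.22 ± 0.15 and 2.21 ± 0.15. The lipoprotein receptor Vldlr rose by 1.93, the sulfotransferase Sult3a1 by 1.90 and the acyltransferase Mogat2, which makes diacylglycerol, by 1.89. The largest fall was that of Tff3, a secreted trefoil peptide, by 2.31 ± 0.13, or 4.96-fold, from 1.81 ± 1.67 on HFD to -0.50 ± 1.67 on EtOH (SD, n = 45 each).

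Further large rises were those of Cyp26b1, which breaks down retinoic acid (1.76), the glutathione transferase Gsta2 (1.65), the fatty acid hydroxylase Cyp4a14 (1.64), the stress-induced pseudokinase Trib3 (1.56) and Prom1 (1.55). The steroid enzyme genes Hsd3b4 and Hsd3b5, the latter on the male-typical list, fell by 1.70 and 1.14, and Slco1a1, an organic anion uptake transporter, fell by 1.47. Fabp5, a fatty acid binding protein, changed by -1.31, the desmosomal gene Dsg1c by -1.27, the succinate receptor Sucnr1 by -1.17, the peroxisomal coenzyme A hydrolase Nudt7 by -1.11, Serpina9 by -1.11 and the actin nucleator Fmn2 by -1.09. The neutrophil granule genes Mpo and Camp changed by -1.23 and -1.11. These 24 genes were chosen among those with the sign of the mean in at least 12 strains. Cyp2a4 and Cyp2a5 are near-identical in sequence, and Hsd3b4 and Hsd3b5, Gsta2 and Gsta1, and Cyp4a14 and Cyp4a10 are also alike, so their probes may not separate them. A further probe of Abcc4 gave 0.96, one of Cyp2a4 gave 1.33, one of Vldlr gave 1.32, one of Prom1 gave 0.93, one of Trib3 gave 0.77 and one of Fmn2 gave -0.08, against 2.85, 2.22, 1.93, 1.55, 1.56 and -1.09 for the chosen probes.

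In all, 7759 of 17572 genes passed limma's test at an adjusted p under 0.05, of which 3512 rose and 4247 fell. Most changes were small: 284 of these genes changed at least 1.5-fold and 59 at least 2-fold. The adjusted p was 2.33e-24 for Abcc4 and 2.08e-22 for Tff3. Fitted alone with diet as the only term, batches 1 to 5 gave 8, 94, 0, 194 and 197 genes with limma, and 2135, 2027, 1683, 2873 and 2779 genes at an unadjusted p under 0.05. These fits held fewer arrays and no strain term, and they compared mostly different strains between the diets. A grouping by the second strain entry of the labels gave 4062.

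**Figure D1:**
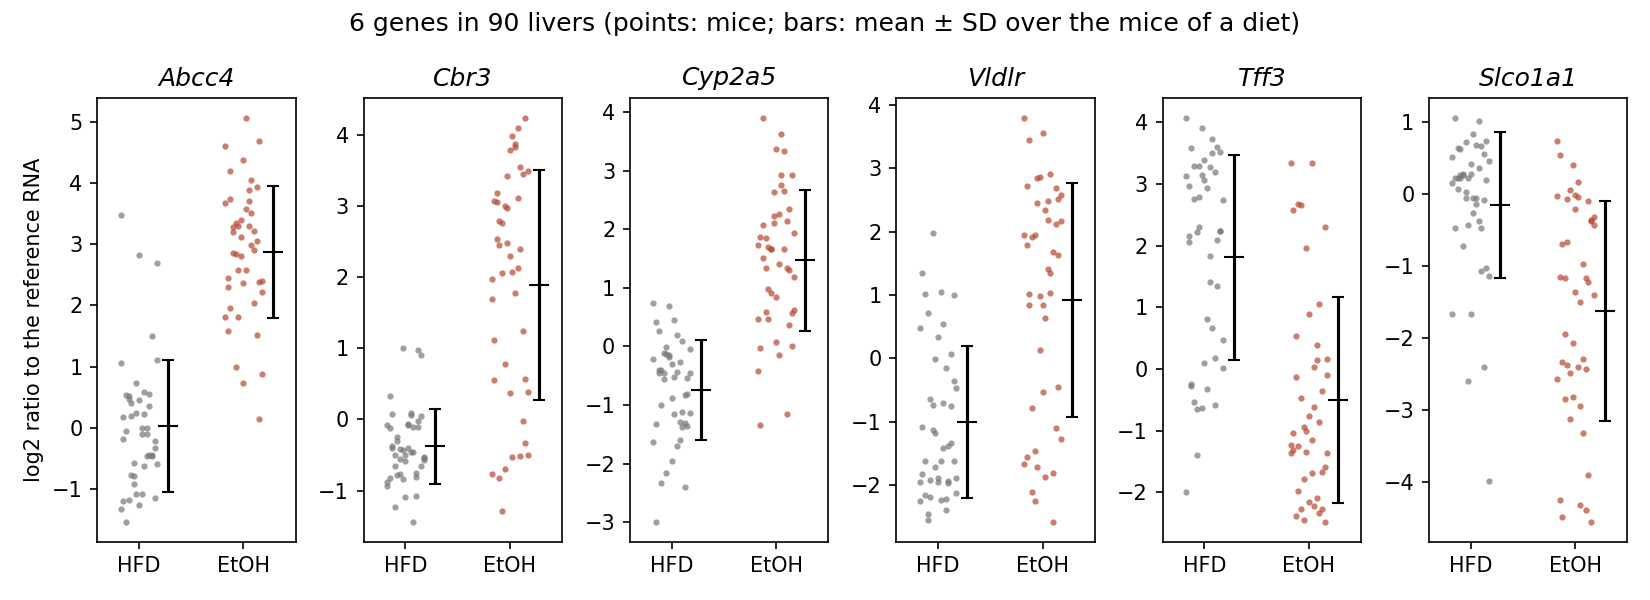
Log2 ratio to the reference RNA (vertical axis) of 6 genes in each of 90 livers, split by diet, with points for mice and bars for the mean ± SD of 45 mice. Abcc4, Cbr3, Cyp2a5 and Vldlr lay higher on EtOH, with a mean Abcc4 ratio of 2.88 against 0.03, and Tff3 and Slco1a1 lay lower.

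Many genes of detoxification rose. Of 22 measured genes of glutathione metabolism and Nrf2 targets, 15 rose, 1 fell (Gstm6, by -0.21) and 6 did not pass the test; 16 rose and 1 fell adjusted over the list alone. Cbr3 led them, with Gsta2, the quinone reductase Nqo1 (1.01) and Gstm4 (0.92). The mean change of the list was 0.63 ± 0.05 (SE), and its median was above 0 in 15 of 15 strains (camera, adjusted p = 7.59e-11). The difference of the diet means within a batch, which compares mostly different strains, was above 0 in all 5 batches. Of 25 measured xenobiotic P450 genes 18 rose and 0 fell (19 and 0 adjusted over the list alone, list mean 0.43 ± 0.04, adjusted p = 2.96e-10), among them Cyp2a5, Cyp3a41a (0.85), Cyp1a1 (0.71) and Cyp2c29 (0.39).

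Most measured genes typical of female liver rose, and most of those typical of male liver fell. Of 12 measured female-typical genes 10 rose and 0 fell, the same counts adjusted over the list alone, with a mean change of 0.72 ± 0.06 (SE; adjusted p = 4.28e-08). Examples were the nucleotidase Nt5e (0.93), the acyl-CoA thioesterase Acot3 (0.85), Sult3a1 and Cyp3a41a. Of 13 measured male-typical genes 9 fell and 1 rose (Cyp2d9, by 0.14), also the same adjusted over the list alone, with a mean change of -0.58 ± 0.06. Elovl3, a fatty acid elongase, changed by -1.02 and the oxysterol hydroxylase Cyp7b1 by -0.99, beside Hsd3b5 and Slco1a1. The male-typical list had an adjusted p of 9.52e-05, and adjusted p = 0.191 with an estimated correlation.

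Genes of lipid handling split by pathway. Of 15 lipid droplet and lipid uptake genes 11 rose and 2 fell (Lpl by -0.45 and Cideb by -0.13), the same adjusted over the list alone, with a mean change of 0.47 ± 0.05 (SE; adjusted p = 1.10e-05). Vldlr led, followed by the fatty acid transporter Cd36 (0.90), the nuclear receptor Pparg (0.46) and the fatty acid binding protein Fabp4 (0.66). Of 24 fatty acid oxidation genes, many of them targets of PPARα, 15 rose and 1 fell (Ppara itself, by -0.27), or 15 and 2 adjusted over the list alone, with Cyp4a14, Vnn1 (1.07), the thioesterase Acot2 (0.80) and Cyp4a10 (0.48, with further probes at 0.65 and -0.15) in front (mean 0.27 ± 0.04, adjusted p = 3.20e-05). That list had an adjusted p = 0.499 with an estimated correlation.

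Many genes of lipid synthesis fell on EtOH. Of 24 cholesterol synthesis genes 19 fell, among them Insig1 (-0.57, with a further probe at -0.21), Mvd (-0.51) and Pmvk (-0.41), the same number adjusted over the list alone (mean -0.29 ± 0.06, SE; adjusted p = 8.84e-06, and adjusted p = 0.575 with an estimated correlation). Of 20 fatty acid synthesis genes 11 fell, among them the citrate lyase Acly (-0.58), the acyltransferase Gpam (-0.62), Elovl5 (-0.50) and Pnpla5 (-0.53). In the same list Scd2 rose by 0.48, Elovl6 by 0.21 and Dgat2 by 0.20, and the counts were the same adjusted over the list alone. The list had a mean of -0.22 ± 0.05, an adjusted p of 0.0247, and adjusted p = 0.575 with an estimated correlation.

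Some markers of immune cells and responses fell on EtOH in the mean over strains. Of 19 interferon response genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), led by Ifit1 (-0.69), Oas1a (-0.35), Mx2 (-0.32) and Ifi44 (-0.41, but -0.03 by a further probe that did not pass), with a list mean of -0.20 ± 0.06 (SE) that was above 0 in batch 2 (0.19). Of 12 neutrophil genes 6 fell and 0 rose (7 and 0 adjusted over the list alone): Camp, Mpo, Ltf (-0.95), Elane (-0.30), Ngp (-0.52) and S100a9 (-0.66). Of 21 acute-phase genes 10 fell and 0 rose, also adjusted over the list alone, among them the fibrinogen genes Fgg (-0.44), Fga (-0.40) and Fgb (-0.45) and Steap4 (-0.43), with a list mean of -0.27 ± 0.10 that was above 0 in batch 3 (0.12). Of 6 MHC class II genes 5 fell (Cd74 by -0.30, Ciita by -0.33, H2-Ab1 by -0.28, H2-Eb1 by -0.38 and H2-Aa by -0.24) and 0 rose, also adjusted over the list alone. The adjusted p was 0.0105 for interferon, 0.0112 for neutrophil, 0.0247 for acute-phase and 0.0444 for MHC class II genes. The interferon, neutrophil and MHC class II lists had adjusted p = 0.575 with an estimated correlation, and the acute-phase list adjusted p = 0.755 with an estimated correlation. The interferon and MHC class II means differed between strains (F tests, adjusted p = 5.09e-05 and 0.00646). For interferon the mean ran from -1.43 in KK/HlJ and -1.03 in C57BL/10J to 0.69 in FVB/NJ and 0.74 in C3H/HeJ. The list median was above 0 in 4 of 15 strains. For MHC class II the mean ran from -1.18 in KK/HlJ to 0.45 in FVB/NJ, with the median above 0 in 2 of 15 strains.

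The MHC class II call (list mean -0.27 ± 0.06) was lost without any of 25 mice, at adjusted p values of up to 0.0736. These were EtOH mice 159 (129S1SvImJ), 181 (BALB/cByJ), 84 (BALB/cJ), 32 (C3H/HeJ), E22 and E30 (C57BL/6J), 142 (FVB/NJ), 296 (KK/HlJ), 292 (MOLF/EiJ) and 336 (PWD/PhJ). The HFD mice were 65 (AKR/J), 272 (BALB/cByJ), 76 (BALB/cJ), 265 (BTBR T+tf/J), 38 (C3H/HeJ), 364 (C57BL/10J), E27 (C57BL/6J), 124 and 132 (DBA/2J), 381 (KK/HlJ), 357 and 360 (MOLF/EiJ), 227 (NZW/LacJ), 393 (PWD/PhJ) and 401 (WSB/EiJ).

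Some genes of damage, matrix and vessel lining rose. Of 17 damage and early stress genes 8 rose, led by Gadd45b (1.28), Gadd45a (0.93), the stress-induced cytokine Gdf15 (0.50) and Ccng1 (0.27), and 1 fell (Bbc3, by -0.26). Of 20 matrix and stellate cell genes 10 rose, such as Sparc (0.32), Fbn1 (0.35) and Mmp13 (0.26), and 1 fell (Timp1, by -0.13), with a list mean of 0.16 ± 0.06 that was -0.02 in batch 3. Of 13 sinusoidal endothelial genes 8 rose, among them Lyve1 (0.88), Vwf (0.48), Eng (0.22) and Tek (0.22), and 1 fell (Stab2, by -0.14), though a further probe of Tek gave -0.06 (adjusted p = 0.0386) and one of Lyve1 gave 0.29. The counts of these 3 lists were the same adjusted over the list alone. Their adjusted p values were 0.00381, 0.0112 and 0.00443, and each had adjusted p = 0.575 with an estimated correlation.

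By camera 15 of 34 lists passed, 8 upward and 7 downward, and the calls that held with an estimated correlation were those of the female-typical list (adjusted p = 0.0152), the glutathione and Nrf2 list (0.0362), the P450 list (0.0362) and the lipid droplet list (0.0366). By fry 20 lists moved one way on balance, which does not set them against other genes. Among 100 splits of the mice within strains 6, the real one included, gave as many lists by camera, up to 16, so chance was not excluded for this count. The median of the other splits was 10 lists. Camera with the preset correlation thus passed many lists under shuffled diets too, and its adjusted p values overstate the evidence for single lists.

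**Figure D2:**
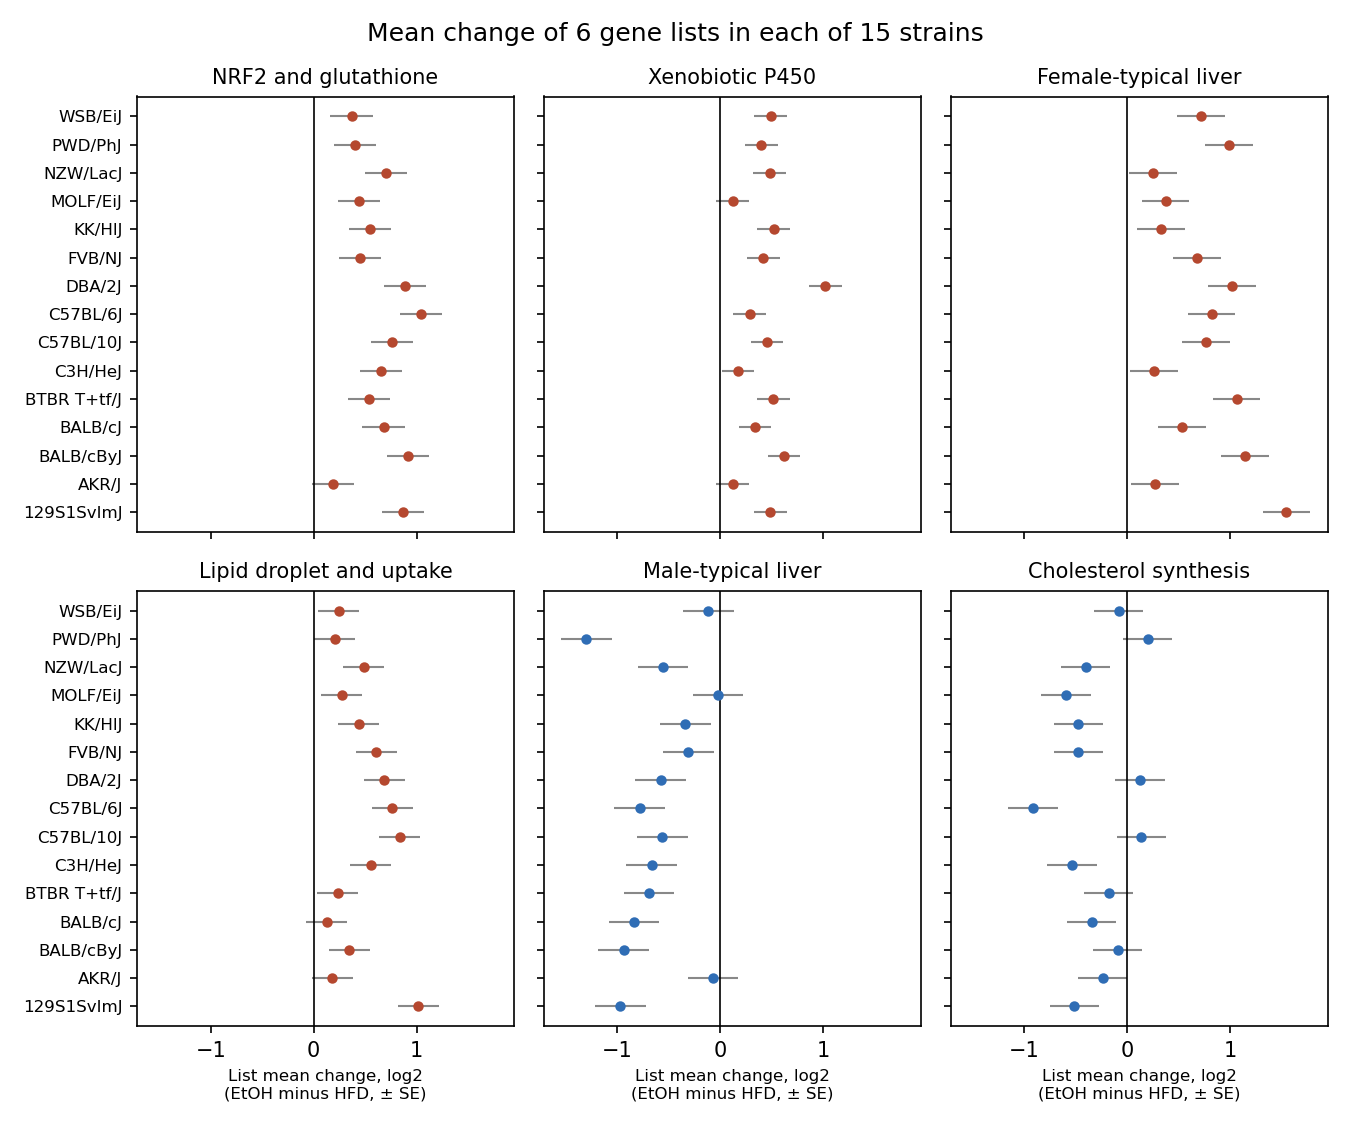
Mean change of 6 gene lists (horizontal axis, log2 EtOH minus HFD) in each of 15 strains, as points with bars of ± SE. The mean of the female-typical list lay above 0 in all 15 strains, from 0.25 in NZW/LacJ to 1.55 in 129S1SvImJ.

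The other 19 lists did not pass camera. Of 13 ethanol oxidation genes 4 rose (Aldh3a2 by 0.67, Adh7 by 0.24, Aldh1a1 by 0.18 and Adh1 by 0.14) and 4 fell (Adh4 by -0.93, Acss2 by -0.42, Adh5 by -0.24 and Cyp2e1, the ethanol-oxidising P450, by -0.18; adjusted p = 0.925). Of 27 methionine and one-carbon genes 9 rose, such as Mat1a (0.69) and Ahcy (0.32), and 8 fell, such as Cbs (-0.25) and Mtr (-0.21; adjusted p = 0.925). Of 25 unfolded protein response genes 4 rose (Trib3, Asns by 0.78, Ddit3 by 0.36 and Atf3 by 0.42) and 4 fell (Edem1 by -0.38, Xbp1 by -0.28, Chac1 by -0.37 and Dnajb9 by -0.22; adjusted p = 0.925). Of 21 bile acid genes 8 rose, with Abcc4, Cyp39a1 (1.40) and Abcc3 (0.63) in front, and 9 fell, with Slco1a1 and Cyp7b1 in front, or 9 and 9 adjusted over the list alone (adjusted p = 0.925). Of 14 circadian genes 5 rose (Tef by 0.65, Cry2 by 0.36, Hlf by 0.29, Nr1d2 by 0.45 and Dbp by 0.59) and 4 fell (Arntl by -0.46, Npas2 by -0.18, Cry1 by -0.28 and Nfil3 by -0.25), or 6 and 4 adjusted over the list alone (adjusted p = 0.438). Of 13 glucose metabolism genes 3 rose (Slc2a2 by 0.49, Fbp1 by 0.25 and Pck1 by 0.33) and the glycogen phosphorylase Pygl changed by -0.16 (adjusted p = 0.559).

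Of 14 iron and heme genes 5 rose (Fth1 by 0.51, Tfrc by 0.73, Ftl1 by 0.27, Alas1 by 0.56 and Id1 by 0.61) and 3 fell (Tmprss6 by -0.10, Hamp2 by -0.34 and Trf by -0.24), or 6 and 3 adjusted over the list alone (adjusted p = 0.0809). Of 25 oxidative phosphorylation genes 4 rose (Ndufb5 by 0.19, Cox4i1 by 0.06, Ndufa5 by 0.07 and Sdhb by 0.09) and 3 fell (Ndufb2 by -0.15, Cycs by -0.11 and Ndufv1 by -0.07), or 1 and 3 adjusted over the list alone (adjusted p = 0.925). Of 20 inflammatory genes 1 rose (Cxcl10, by 0.41) and 2 fell (Spp1 by -0.66 and Il6 by -0.21), or 0 and 1 adjusted over the list alone (adjusted p = 0.925). Of 25 cell cycle genes 2 rose (Mcm2 by 0.38 and Rrm2 by 0.31) and 0 fell (adjusted p = 0.925). Of 13 hepatocyte genes 1 rose (Apoc3, by 0.12) and 1 fell (Apoa1, by -0.36; adjusted p = 0.925). Of 19 Kupffer cell and macrophage genes 1 rose (Cd9, by 0.26) and 2 fell (Clec4f by -0.19 and Timd4 by -0.22), with 0 and 0 adjusted over the list alone (adjusted p = 0.925).

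Of 6 B and plasma cell genes 4 fell (Cd79b by -0.31, Jchain by -0.46, Pou2af1 by -0.25 and Ms4a1 by -0.23) and 0 rose (adjusted p = 0.0734, passing without EtOH mouse 32 of C3H/HeJ at 0.0499, EtOH mouse 126 of DBA/2J at 0.0457 or HFD mouse 385 of KK/HlJ at 0.0414). Of 5 erythroid genes 3 fell (Alas2 by -0.49, Slc4a1 by -0.29 and Ahsp, named Eraf in the files, by -0.29; adjusted p = 0.176). Of 6 cholangiocyte genes 1 rose (Prom1) and 1 fell (Sox9, by -0.34; adjusted p = 0.179). Of 12 pancreatic acinar genes 1 fell (Amy2, by -0.24; 0 adjusted over the list alone; adjusted p = 0.380). Of 11 T and NK cell genes, 4 adipocyte genes and 5 skeletal muscle genes 0 passed limma's test (adjusted p = 0.925, 0.925 and 0.438 by camera). Unless stated, counts were the same adjusted over the list alone. Median, mean and camera differed in sign for the ethanol oxidation, methionine, unfolded protein response, bile acid, inflammatory and cell cycle lists.

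Of the members named for these lists, the tetraspanin Cd9, the chemokine Cxcl10, the cytokine Il6 and the macrophage receptor Timd4 passed narrowly and lost their calls without single mice. Cd9 did so without mouse 160, 63, 84, 75, 40, 378, 134, 123, 302, 229, 336 or 401 (adjusted p up to 0.0603). Cxcl10 did so without mouse 156, 174, 276, 79, 267, 40, 370, 378, 19, E28, 123, 150, 151, 302, 306, 288, 223, 327 or 318 (up to 0.0639). Il6 did so without mouse 159, 160, 278, 280, 50, 65, 171, 276, 79, 85, 27, 76, 200, 266, 267, 32, 36, 38, 370, 379, 377, 378, 19, E30, E27, E29, 126, 124, 142, 149, 150, 296, 304, 385, 288, 292, 357, 360, 223, 228, 229, 327, 336, 393, 398, 308, 315 or 318 (up to 0.0786). Timd4 did so without mouse 159, 281, 65, 181, 272, 85, 76, 267, 6, 364, E30, E27, 121, 124, 149, 302, 381, 292, 360, 228, 336, 393, 308 or 315 (up to 0.0683). Further probes gave smaller changes that passed for Nt5e (0.35), Abcc3 (0.25), Acss2 (-0.14 and -0.29), Edem1 (-0.15 and -0.24), Gadd45b (0.84) and Slc2a2 (0.33). They did not pass for Ccng1 (0.09), Cd9 (0.10), Adh1, Pygl, Timp1, Dnajb9 (-0.17 and -0.13), H2-Aa (-0.19) and H2-Ab1 (-0.18 and -0.20, with another at -0.24 that passed). Of 3 further probes of Tef (0.35, 0.20 and 0.02) the last did not pass.

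Other members of the lists did not pass with all mice but passed without single mice, with the lowest adjusted p in brackets. Nkg7 did so without mouse 63, 64, 27, 36, 378, 126, 123, 141, 150, 306, 385, 286, 360, 227 or 399 (down to 0.0158). Cd3d passed without mouse 32 or 306 (0.0307), Cd8b1 without 156 or 302 (0.0383), Car3 without 65 or 79 (0.0375) and Mylpf without 370 (0.0372). Cpa1 passed without mouse 159, 280, 281, 43, 50, 179, 85, 27, 200, 267, 36, 40, 379, 378, 19, E27, 126, 124, 142, 149, 150, 302, 381, 286, 356, 217, 231, 227, 327, 308, 315 or 318 (down to 0.0299). Icam1 passed without mouse 159, 65, 27, 32, 36, 379, 126, 124, 149, 296, 381, 292, 223 or 315 (down to 0.0176), Itgam without 63 or 286 (0.0214) and Tk1 without 40 (0.0336).

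Within single strains, only called genes with a symbol above background on all 6 arrays of the strain were ranked by size. Among these Tff3 was the largest fall in 8 of 15 strains, and Abcc4 and Sult3a1 were each the largest rise in 3. In 129S1SvImJ, Cyp4a14 rose by 5.85 ± 0.66 (SE) and Saa2, an acute-phase protein, changed by -3.70, and 843 genes rose and 953 fell. In AKR/J 7 genes passed, the fewest of any strain: Pyroxd2 (0.79), Nenf (0.68), Cmss1 (0.57), Nubpl (0.51) and LOC245651 (0.38) rose, Tff3 changed by -2.64 and Ywhaz by -0.74. In BALB/cByJ the sulfotransferase Sult2a2 rose by 4.54 and Slco1a1 changed by -3.27 (302 genes rose, 112 fell). In BALB/cJ Cbr3 rose by 3.44 and Hsd3b4 changed by -2.82 (91 and 36), and in BTBR T+tf/J Cyp4a14 rose by 4.21 and Tff3 changed by -2.95 (478 and 285). All counts and changes are from limma with n = 3 mice per diet, adjusted within the strain. The EtOH and HFD mice of a strain lay mostly in different batches, so these values also rest on the batch terms. The counts of 1796 in 129S1SvImJ, 7 in AKR/J, 414 in BALB/cByJ, 127 in BALB/cJ and 763 in BTBR T+tf/J moved over 1.5 times without single mice. In 129S1SvImJ they were 400, 3319 and 975 without EtOH mice 156, 159 and 160, and 689 and 1082 without HFD mice 280 and 281. In AKR/J they were 11 and 130 without EtOH mice 43 and 50, 11 without EtOH mouse 327 of PWD/PhJ, and 0 without HFD mouse 65 (591 at an unadjusted p under 0.05). In BALB/cByJ they were 115 and 129 without EtOH mice 171 and 181, and 150 and 93 without HFD mice 272 and 276. In BALB/cJ they were 28 without EtOH mouse 84, and 80, 35 and 57 without HFD mice 27, 75 and 76. In BTBR T+tf/J they were 472, 289 and 363 without EtOH mice 189, 196 and 200, and 356, 301 and 442 without HFD mice 265, 266 and 267. Without single mice Pyroxd2 and Tff3 also lost their calls in AKR/J (EtOH 49 with adjusted p of 0.0696 and 0.147, HFD 65 with 0.397 and 0.361), and Hsd3b4 its call in BALB/cJ (EtOH 84 and 85 with 0.269 and 0.0703, HFD 75 and 76 with 0.0913 and 0.0703).

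In C3H/HeJ Abcc4 rose by 2.76 and Tff3 changed by -2.23, and 88 genes rose and 180 fell. In C57BL/10J Sult3a1 rose by 3.76 and Tff3 changed by -3.12 (527 and 365). In C57BL/6J Mogat2 rose by 3.58 ± 0.46 (SE) and Tff3 changed by -4.50 ± 0.50, the largest fall of Tff3 in any strain (209 and 178). In DBA/2J Abcc4 rose by 4.78 and Tff3 changed by -3.41 (252 and 265), and in FVB/NJ by 2.95 and -2.64 (630 and 327). The counts of 268 in C3H/HeJ, 892 in C57BL/10J, 387 in C57BL/6J, 517 in DBA/2J and 957 in FVB/NJ moved over 1.5 times without single mice. In C3H/HeJ they were 1032, 941 and 26 without EtOH mice 32, 36 and 40, 82, 41 and 47 without HFD mice 6, 7 and 38, and 406 without EtOH mouse 302 of KK/HlJ. In C57BL/10J they were 518 without EtOH mouse 379, and 388, 506 and 545 without HFD mice 364, 377 and 378. In C57BL/6J they were 164 without EtOH mouse 19, and 156, 252 and 226 without HFD mice E27, E28 and E29. In DBA/2J they were 178 without EtOH mouse 134, and 267, 242 and 299 without HFD mice 123, 124 and 132. In FVB/NJ they were 292 without EtOH mouse 146, and 252 and 372 without HFD mice 150 and 151. In C3H/HeJ the Abcc4 call was lost without EtOH mouse 40 (adjusted p = 0.256) and the Tff3 call without HFD mice 38 and 7 (0.0630 and 0.0665), and in C57BL/10J the Sult3a1 call without HFD mouse 378 (0.0551).

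In KK/HlJ the chemokine receptor Ackr3 rose by 3.05 and the chitinase-like macrophage gene Chil3 changed by -3.14, and 560 genes rose and 907 fell. In NZW/LacJ Cyp2a4 rose by 3.83 and the anion exchanger Slc26a4 changed by -3.01 (634 and 372). In PWD/PhJ Prom1 rose by 3.92 and Hsd3b4 changed by -3.69 (215 and 364). In WSB/EiJ Sult3a1 rose by 4.09 and Tff3 changed by -2.32 (58 and 75), and in MOLF/EiJ Sult3a1 rose by 3.66 and the inositol phosphate kinase Ip6k2 fell 2.82-fold (16 and 13). The counts of 1467 in KK/HlJ, 1006 in NZW/LacJ, 579 in PWD/PhJ, 133 in WSB/EiJ and 29 in MOLF/EiJ moved over 1.5 times without single mice. In KK/HlJ they were 2413, 167 and 2269 without EtOH mice 296, 302 and 304, and 958 and 923 without HFD mice 381 and 385. In NZW/LacJ they were 394 without EtOH mouse 223, and 644, 532 and 650 without HFD mice 227, 228 and 229. In PWD/PhJ they were 1024 and 116 without EtOH mice 327 and 336, 262 and 241 without HFD mice 393 and 399, and 899 without EtOH mouse 40 of C3H/HeJ. In WSB/EiJ they were 21, 83 and 40 without EtOH mice 308, 309 and 314, and 7, 54 and 1151 without HFD mice 315, 318 and 401. In MOLF/EiJ they were 69, 9 and 12 without EtOH mice 286, 288 and 292, 19, 13 and 11 without HFD mice 356, 357 and 360, and 45 and 44 without EtOH mice 156 of 129S1SvImJ and 302 of KK/HlJ. Calls of named genes were lost for Ackr3 without KK/HlJ EtOH mouse 302 (adjusted p = 0.0982), for Sult3a1 in WSB/EiJ without HFD mouse 315 (0.103) and for Tff3 there without EtOH mouse 308 or HFD mouse 315 (0.0804 and 0.620). In MOLF/EiJ Ip6k2 lost its call without EtOH mice 288 and 292 (0.110 and 0.0739) and HFD mice 356, 357 and 360 (0.0627, 0.0869 and 0.12), and Sult3a1 (0.0462 with all mice) without any of 39 mice, with EtOH mice 288 and 292 at 0.255 and 0.272, HFD mice 356, 357 and 360 at 0.110, 0.101 and 0.319, and mice 278, 281, 64, 171, 276, 84, 75, 189, 200, 265, 266, 267, 32, 36, 6, 7, 370, 364, E22, E28, E29, 123, 124, 141, 306, 381, 217, 223, 227, 228, 229, 308, 309 and 314 of other strains at up to 0.0567.

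**Figure D3:**
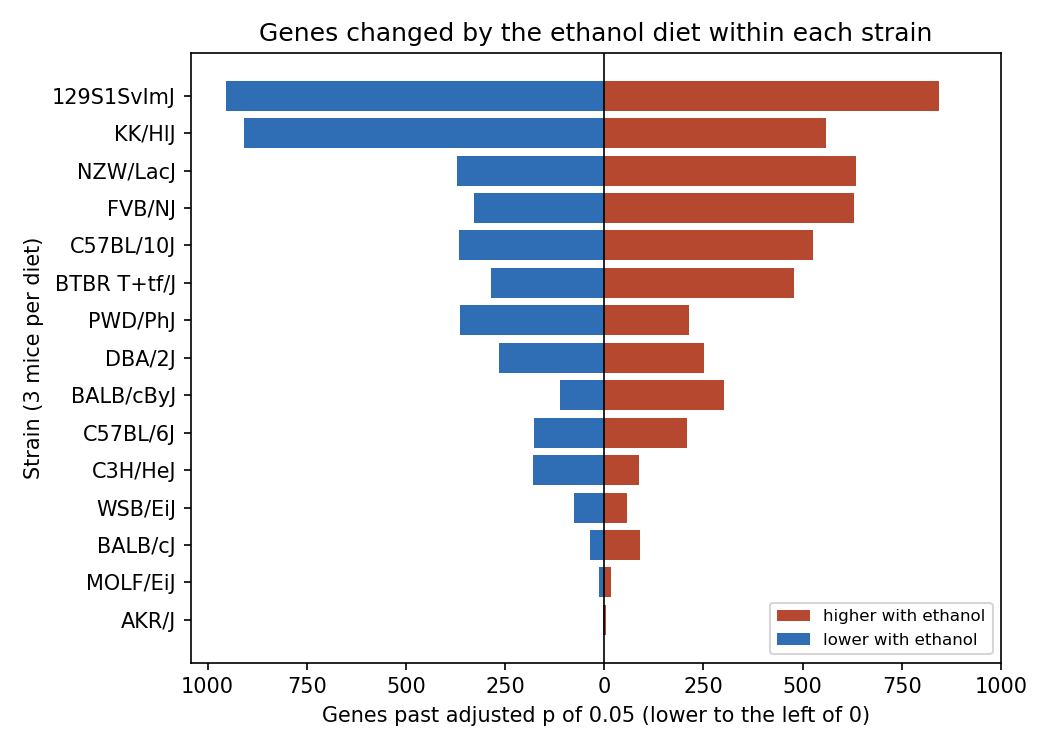
Number of genes that rose or fell on EtOH (horizontal axis, adjusted p under 0.05 within the strain) in each of 15 strains with 3 mice per diet. The counts ran from 7 in AKR/J to 1796 in 129S1SvImJ.

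Abcc4 was called up in 12 strains and Tff3 called down in 12, the most of any gene each way. Among the 5 genes named each way, next came Cdpf1 (11 strains, mean 0.76 ± 0.05, SE) and Cbr3, Trib3 and Rian, a noncoding RNA of an imprinted region (10 strains each, Rian mean 1.36 ± 0.09). Other genes tied with them: 3 genes were called up in at least 11 strains and 10 in at least 10, and 12 were called down in at least 8. Downward, the histone gene H2ac18 was called in 11 strains (-0.62), Dsg1c in 10, the complement gene C6 in 9 (-1.05) and Fmn2 in 8. In all, 232 genes were called the same way in at least 5 strains (165 up, 67 down; 1631 with array weights, or 1039 with weights estimated gene by gene, 519 with ComBat, 366 and 438 without arrays of weight under 0.2 and 0.25, and 0 by the second strain entry), and 162 genes were called up in some strain and down in another. The strain effects were 9342 calls in sum (4908 up, 4434 down), with 42770 at an unadjusted p under 0.05. The sum was 37951 with array weights (28543 gene by gene), 16530 with ComBat, 14083 without arrays of weight under 0.25 and 3720 by the second strain entry.

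The interaction of strain and diet asks which genes answered ethanol differently between strains. Cyp4a14 rose by 5.85 ± 0.66 (SE) in 129S1SvImJ and stood at -1.13 ± 0.66 in PWD/PhJ (adjusted p = 0.375 in that strain). Sult2a2 rose by 4.54 ± 0.53 and the glucuronosyltransferase Ugt1a9 by 2.24 ± 0.27 in BALB/cByJ, while both were lowest in MOLF/EiJ (-0.29 and -0.18), where Sult2a2 lay above background on 1 of 6 arrays. Vldlr rose by 3.26 ± 0.43 in DBA/2J and stood at -0.24 in PWD/PhJ. In PWD/PhJ the collagen gene Col22a1 rose by 1.93 ± 0.18, the nuclease gene Dnase1 changed by -2.35 ± 0.27 and Dpy19l3 by -1.61 ± 0.22. Ly6i, a surface antigen gene, rose by 1.45 ± 0.16 in C3H/HeJ, the keratin Krt23 by 2.90 ± 0.36 in NZW/LacJ, and the kinase gene Ptk2b changed by -1.37 ± 0.18 in C57BL/6J. Each SE pools the spread of a gene over all groups, and some of these groups varied more than it shows. The SD was 2.06 for Cyp4a14 in EtOH mice of 129S1SvImJ. On EtOH and HFD it was 0.39 and 0.66 for Ly6i in C3H/HeJ and 0.60 and 0.79 for Dnase1 in PWD/PhJ. Other groups varied little, as for Dpy19l3 in PWD/PhJ (0.06 and 0.14). Over 15 strains further probes gave 0.46 for Sult2a2, -0.13 for Dpy19l3, -0.12 for Ptk2b and 0.17 for Col22a1, against 1.17, -0.53, -0.30 and 0.27 for the chosen probes.

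The test of the interaction itself (limma's F test over 15 strains) passed for 1378 genes, with adjusted p values of 1.52e-07 for Ly6i and 2.84e-06 for Cyp4a14. Of these genes 863 also passed in the mean over strains, 1270 were called in at least 1 strain and 139 were called up in 1 strain and down in another. The count was 2222 without HFD mouse 401 of WSB/EiJ, and 678 without the 3 wild-derived strains. It was 12404 with array weights (9332 gene by gene), 4003 with ComBat, 2204 with no background correction, 2357 and 3421 without arrays of weight under 0.2 and 0.25, and 738 by the second strain entry.

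Strain differences on HFD alone were wide. Rpl14, a ribosomal protein gene, was highest in DBA/2J (1.90 ± 0.05, SD, n = 3) and lay below -1 in 4 strains, BTBR T+tf/J, MOLF/EiJ, PWD/PhJ and WSB/EiJ. Wdr48 was high in PWD/PhJ (2.63), MOLF/EiJ and BTBR T+tf/J and near 0 elsewhere, while Commd5 lay at -4.09 in MOLF/EiJ and near 0 in the other strains. Eola1 was low in MOLF/EiJ (-2.55) and PWD/PhJ, Tceanc2 in DBA/2J (-2.84) and NZW/LacJ, and Reep3 in NZW/LacJ (-2.82), PWD/PhJ and MOLF/EiJ. Abhd1 was highest in 129S1SvImJ (3.52) and lowest in DBA/2J (-0.77), and Dcun1d1 was low in FVB/NJ, MOLF/EiJ (-2.21) and PWD/PhJ. Tomm22, a subunit of the mitochondrial import receptor, was lowest in PWD/PhJ (-2.20) and highest in C57BL/10J (0.08), and Yae1d1 was lowest in PWD/PhJ (-1.98) and highest in KK/HlJ (0.06). By limma's F test 12131 genes (69.0%) differed among strains. Among the genes named here the adjusted p ran from 2.15e-36 for Rpl14 to 1.03e-30 for Yae1d1. The count was 7722 without the 3 wild-derived strains and 4041 by the second strain entry, and 75% of 520 further probes followed the chosen probe among genes with over 4-fold differences, so a sequence variant under a probe was not separated from a difference in RNA. Rpl14, Wdr48, Eola1, Tomm22 and Commd5 had 1 probe each, so no further probe speaks to them.

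Between the C57BL substrains on HFD, Sec14l4, a lipid transfer protein gene, was 12.6-fold higher in C57BL/6J than in C57BL/10J (3.66 ± 0.21, SE, n = 3 each). The clock-controlled factor Dbp (2.52 ± 0.70), the clock repressor Nr1d2 (1.84), the noncoding RNA Malat1 (1.97) and the kinase Aatk (1.81) were also higher in C57BL/6J. The sulfotransferase Gal3st1 (-2.67), Myom3 (-2.29), the interferon-inducible Ifi27l2b (-1.94), the histone gene H4c9 (-1.89) and the protease Tmprss4 (-1.89) were lower. Limma called 515 genes, 332 higher and 183 lower in C57BL/6J, with adjusted p of 1.40e-20 for Sec14l4. The count was 220 to 331 without 1 mouse of the pair (C57BL/6J mice E27, E28 and E29 at 331, 220 and 286, C57BL/10J mice 364, 377 and 378 at 268, 253 and 255). Calls were lost for Dbp and Ifi27l2b without each of these 6 mice (adjusted p up to 0.175 and 0.119) and for Nr1d2 without 377, 378 or E27 (up to 0.134). The count was 3888 with array weights and 337 with signal on all arrays, and by the second strain entry 1 gene was called and 6 of the 10 genes named turned direction.

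Between the BALB/c substrains on HFD, Radx was higher in BALB/cJ by 3.21 ± 0.28 (SE, n = 3 each; above background on 1 of 3 BALB/cByJ arrays), Arl2bp by 2.50, the lipoprotein lipase gene Lpl by 2.48, Otud3 by 2.44 and Cspg5 by 2.42. Lower in BALB/cJ were the lysophospholipid transporter Mfsd2a (-3.13 ± 0.79), Defb19 (-3.13), Pate5 (-2.98), the DNA polymerase Dntt (-2.96) and Armcx6 (-2.63). Limma called 311 genes, 112 higher and 199 lower in BALB/cJ, with adjusted p of 1.81e-22 for Otud3. The count was 175 without BALB/cByJ mouse 276 and 152 without BALB/cJ mouse 75. It was 616 with array weights and 189 with signal on all arrays, and by the second strain entry 9 of the 10 genes named turned direction. The call of Lpl was lost without mouse 276 (adjusted p = 0.0557) and that of Mfsd2a without BALB/cByJ mice 179 and 276 (0.116 and 0.0691) or BALB/cJ mice 75 and 76 (0.114 and 0.0929).

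**Figure D4:**
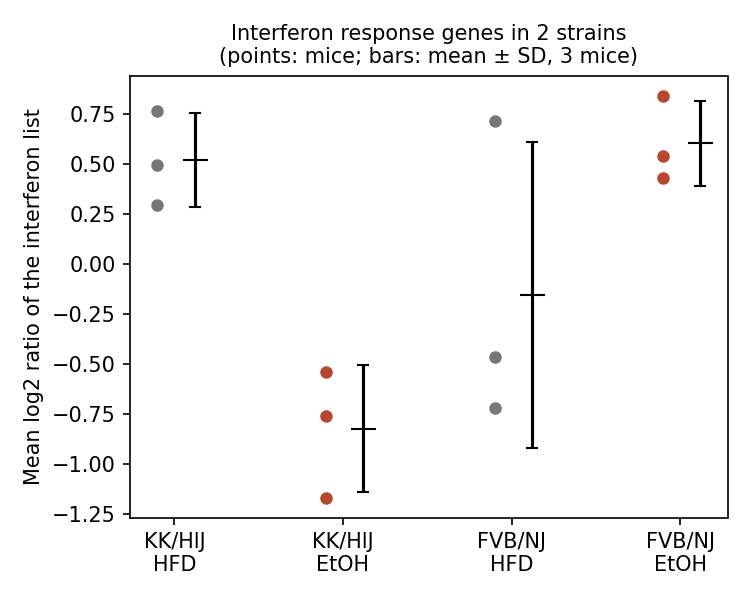
Mean log2 ratio of the interferon response list (vertical axis) in mice of KK/HlJ and FVB/NJ by diet, with points for mice and bars for the mean ± SD of 3 mice. In KK/HlJ the mean was 0.52 on HFD and -0.82 on EtOH, and in FVB/NJ -0.16 and 0.60.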

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

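The splits of the mice were planned, and the tests of the interferon pattern, of the numbers of genes per strain and of the over 4-fold strain differences were chosen only after the results were seen. A difference between strains in the answer to ethanol singled out 1378 genes and 6 lists by a test of the difference itself. Among genes with a symbol that lay above background on at least 45 arrays, those of smallest adjusted p were Ly6i (1.52e-07), Cyp4a14 (2.84e-06), Dpy19l3 (2.84e-06), Sult2a2 (1.12e-05), Ugt1a9 (1.76e-05), Ptk2b (2.35e-05), Vldlr (2.35e-05), Col22a1 (2.37e-05), Dnase1 (2.99e-05) and Krt23 (5.38e-05). Fatty acid oxidation genes differed between strains (adjusted p = 0.00136), with list means from 1.03 in 129S1SvImJ to -0.23 in PWD/PhJ. Interferon response genes did so at 5.09e-05, female-typical genes at 0.0145, T and NK cell genes at 0.00646, MHC class II genes at 0.00646 and pancreatic acinar genes at 0.0159.

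On average, interferon response genes moved in opposite directions in KK/HlJ and FVB/NJ. Their list mean changed by -1.43 ± 0.25 (SE) in KK/HlJ and by 0.69 ± 0.25 in FVB/NJ, a difference of 2.13 ± 0.345, and C3H/HeJ (0.74) and C57BL/10J (-1.03) also lay far apart. Batch terms did not remove the difference, in a test written after the others. It was 2.11 ± 0.35 without these terms and 6.17 SE with them, while 6816 genes differed between batches. The terms assume the same batch shift in every strain, and in each of these strains the diets shared only a single batch. A batch effect particular to a strain was therefore not excluded. None of 12 left-out mice turned either sign (KK/HlJ -1.59 to -1.18, FVB/NJ 0.45 to 1.09). A kept sign is a weak test of the rise in FVB/NJ, where the HFD mice varied widely (SD 0.77). HFD mouse 149 there stood at 0.72, above EtOH mice 142 and 146 (0.54 and 0.43). Mice 146 and 149 were the only FVB/NJ mice of different diets in the same batch, and their order went against the rise. In KK/HlJ the mice that shared a batch were EtOH mouse 304 (-0.76) and HFD mouse 306 (0.30), in the order of the fall. The SE pools the spread of all groups, so the rise in FVB/NJ is less certain than it shows. A lower share of hepatocyte RNA in one group was not excluded, because 0 of 5 other cell type lists moved against the interferon list by over 2 SE: macrophage (0.95 ± 0.29), T and NK cell (0.47 ± 0.12), endothelial (0.43), cholangiocyte (0.69) and matrix lists (0.68) moved with it in FVB/NJ, and macrophage (-0.87) and T and NK cell lists (-0.46) in KK/HlJ, where endothelial (0.13 ± 0.16), cholangiocyte (0.14 ± 0.21) and matrix lists (0.08 ± 0.22) had the other sign and MHC class II genes, outside this test, changed by -1.18 ± 0.24. A strain difference in the answer to ethanol and a difference in immune state between animals both remain possible with 3 mice per group.

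The number of genes called ran from 7 in AKR/J to 1796 in 129S1SvImJ. Array quality may play a part, but over 15 strains the number had rho = -0.0893 with the lowest array weight (permutation p = 0.752, adjusted 0.752; r = -0.139, p = 0.619, adjusted 0.619; r = -0.143 without the 2 farthest strains). With the spread within the strain rho was 0.182 (p = 0.516, adjusted 0.752; r = 0.365, p = 0.183, adjusted 0.521; r = 0.245 without the 2 farthest), and with the signal difference between diets it was -0.229 (p = 0.411, adjusted 0.752; r = -0.261, p = 0.348, adjusted 0.521; r = -0.171 without the 2 farthest). None of these passed, and 15 strains leave weak relations open. The fit used a spread shared by all strains for each gene, so a smaller spread within a strain could not itself raise its count. A larger spread could do so, but that relation did not pass either. Neither array quality, a larger spread, the signal difference nor a true difference in sensitivity to ethanol was excluded.

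Over 4-fold differences among strains on HFD were found for 1232 genes, such as Rpl14, Commd5 and Abhd1. Sequence variants under the probes could explain some of them, since 75% of 520 further probes followed the chosen probe, short of the 80% set as a bound, and 11.3% had a correlation below 0. The median range over strains was 1.46 on the log2 scale for the further probes, against 2.54 for the chosen probes. Rpl14 and Commd5 had 1 probe each, so this comparison does not cover them. Mislabelled strains are unlikely to explain it, since 92.2% of mice (83 of 90) correlated best with another mouse of their title strain, a test written after the others, against 57.8% (52) by the second strain entry.

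Among 100 splits of the mice within strains, the real one alone reached its count for the mean over strains (7759 genes, highest other 1) and the sum over strains (9342 against 1531). The same held for the interaction (1378 against 169) and for genes called the same way in 5 strains or more (232 against 0). A chance split is thus an unlikely source of these counts, the interaction aside. The splits remove any shared diet effect, so they cannot test the interaction against an equal effect in every strain. Among 100 shuffles of strain names among the HFD mice, the real one alone reached its count of strain differences on HFD (12131 against 3182). Chance was not excluded for the lists, where 6 of the splits within strains gave as many (15 lists against up to 16, with a median of 10 in the other splits). For single strains 10 splits are too few to exclude chance, with 1 split (the real one) as large and the highest other at 571 in 129S1SvImJ (real 1796), 9 in BALB/cByJ (414), 9 in BALB/cJ (127), 0 in BTBR T+tf/J (763), 4 in C3H/HeJ (268), 4 in C57BL/10J (892), 6 in C57BL/6J (387), 14 in DBA/2J (517), 160 in FVB/NJ (957), 500 in KK/HlJ (1467), 27 in NZW/LacJ (1006) and 83 in PWD/PhJ (579). In AKR/J 3 splits were as large (7 against up to 261), in MOLF/EiJ 2 (29 against 37) and in WSB/EiJ 3 (133 against 312). For the substrain pairs 10 splits are likewise too few, with 515 against 1 for C57BL/6J and C57BL/10J and 311 against 25 for BALB/cJ and BALB/cByJ.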

How the results depend on the processing

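No paired analysis was possible because replicate numbers name single animals that no other group shares. The arrays of low weight were left out, and weights estimated gene by gene, only after the data were seen; the other settings were planned, and those of scan date (identical to batch) and averaged further arrays (a repeated common RNA) were not run. The count over 15 strains was 6336 (well above background on all arrays) to 9599 (array weights) under settings with all strains, and 7091 to 8008 without 1 strain. Without 1 mouse it was 7595 to 8086, for the sum over strains 8088 to 11693, the interaction 1067 to 2222, strain differences on HFD 11649 to 12579, C57BL/6J against C57BL/10J 220 to 613, BALB/cJ against BALB/cByJ 152 to 343, genes called in 5 strains or more 188 to 304 and lists 14 to 16. A lone remaining mouse was assumed to vary like other groups.

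The count over 15 strains fell to 8, 94, 0, 194 and 197 within batch 1 to 5 alone (18 arrays each, unadjusted p under 0.05 by limma for 2135, 2027, 1683, 2873 and 2779 genes). These fits held fewer samples and no strain term, and the EtOH and HFD arrays of a batch came mostly from different strains. With the strain from the second strain entry of the labels (14 strains), EtOH against HFD over 15 strains gave 4062, the sum over strains 3720, the interaction 738, strain differences on HFD 4041, C57BL/6J against C57BL/10J 1, and genes called in 5 strains or more 0. With array weights the sum over strains was 37951, the interaction 12404, C57BL/6J against C57BL/10J 3888, BALB/cJ against BALB/cByJ 616 and genes called in 5 strains or more 1631. The REML fit of these weights stopped before it converged; weights estimated gene by gene (rho = 0.982 with them) gave 28543, 9332, 3548, 617 and 1039, and lost the same list calls. With ComBat in place of the batch term they were 16530, 4003, 874 (C57BL pair) and 519. With no background correction the interaction was 2204 and the C57BL pair 816. With signal on all arrays (12405 genes) the C57BL pair gave 337 and the BALB/c pair 189. Without the 3 wild-derived strains the interaction was 678 and strain differences 7722. Without arrays of weight under 0.2 (4 arrays) the interaction was 2357, the C57BL pair 818 and genes called in 5 strains or more 366; under 0.25 (7 arrays) they were 3421, 1165 and 438, the sum over strains 14083 and the BALB/c pair 467. Lists by camera with an estimated correlation numbered 4. The cause was not tested, except that fewer genes or samples, or no strain term, enter where stated.

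Reversed with the strain from the second strain entry were, in C57BL/6J against C57BL/10J, Aatk (-0.37), Dbp (-1.57), Ifi27l2b (0.77), Malat1 (-0.0056), Nr1d2 (-0.86) and Sec14l4 (-0.0484); in BALB/cJ against BALB/cByJ, Armcx6 (1.93), Cspg5 (-0.0629), Defb19 (1.95), Dntt (1.87), Lpl (-0.10), Mfsd2a (0.94), Otud3 (-0.0496), Pate5 (2.10) and Radx (-1.64); and Saa2 in 129S1SvImJ (1.16), Sult3a1 in C57BL/10J (-1.92), Tff3 in C57BL/10J (0.47) and Tff3 in FVB/NJ (1.77). Within batch 1 alone reversed were Alas1 (-0.27), Amy2 (0.0227), Cd9 (-0.13), Cxcl10 (-0.0235), Mcm2 (-0.0981), Mmp13 (-0.0305), Ndufv1 (0.0899) and Rrm2 (-0.0622). Within batch 2 alone they were Fga (0.15), Fgg (0.0138), Ifi44 (0.18), Ifit1 (0.27), Rrm2 (-0.14), Steap4 (0.0491) and Timp1 (0.0509). Within batch 3 alone they were Apoc3 (-0.0800), Fga (0.0288), Il6 (0.20) and Steap4 (0.0694). Within batch 4 alone they were Ahcy (-0.0104), Apoc3 (-0.0341), Cd79b (0.12), Jchain (0.066), Ms4a1 (0.0132), Pnpla5 (0.00547), Pou2af1 (0.38), Sox9 (0.10) and Timd4 (0.11). Within batch 5 alone they were Cd79b (0.0741), H2-Ab1 (0.0844), Pou2af1 (0.0364), Pygl (0.0521) and Timd4 (0.25). Each batch alone held fewer samples, had no strain term in its fit and compared mostly different strains between the diets. For the strain entry the cause was not tested. Of the list calls, that of MHC class II genes was also lost with array weights, ComBat, the Cy5 channel alone, no background correction, signal on all arrays and without arrays of weight under 0.25, that of fatty acid synthesis genes with array weights, signal on all arrays and without arrays of weight under 0.2 or 0.25, that of interferon genes with array weights and by the second strain entry, that of neutrophil genes with no background correction and signal on all arrays, and that of matrix genes with signal on all arrays. Calls were gained for B and plasma cell genes (the scanner's log ratio, the Cy5 channel alone, dim probes kept), iron and heme genes (mean of all probes, dim probes kept, without arrays of weight under 0.25) and skeletal muscle genes (second strain entry). Signal over background limited the test to 17572 of 27962 genes.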

Other observations

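The permutation test of the lists, the correlations between strains, the comparison of spread and the matching of mice to strains were tests chosen only after results were seen. The list mean of iron and heme genes was above 0 on EtOH (0.13) when diets were permuted within strains, and so was that of cholangiocyte genes (0.27), which Prom1 (1.55) carried while Sox9 fell; each had an adjusted p of 3.8e-05, the smallest the draws allowed after adjustment. The list mean was below 0 for B and plasma cell genes (-0.22, 0.00034) and erythroid genes (-0.21, 0.0045) and above 0 for circadian genes (0.11, 0.0045) and bile acid genes (0.07, 0.04), where Abcc4 (2.85) carried it and 8 genes rose and 9 fell. This test passed 21 lists, among them the 15 of camera, and does not set a list against other genes.

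The correlation of strain effects across genes was above 0 in 100 of 105 pairs of strains, with a median of 0.307, and ran from -0.208 for WSB/EiJ with PWD/PhJ to 0.636 for DBA/2J with 129S1SvImJ. The Y-linked genes Ddx3y (0.81), Eif2s3y (1.1), Uty (0.66) and Kdm5d (0.17) had their highest strain means in C3H/HeJ.

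The median spread within groups was 0.169 on EtOH and 0.142 on HFD, larger on EtOH in 11 of 15 strains (permutation p = 0.0278). The lowest array weights were those of EtOH mice 302 of KK/HlJ (0.107), 40 of C3H/HeJ (0.108), 43 of AKR/J (0.177) and 146 of FVB/NJ (0.192). Over the 1232 genes with over 4-fold strain differences 44 of 45 EtOH mice matched their title strain; DBA/2J mouse 126 had r = 0.278 with its own strain and 0.388 with C57BL/6J. C3H/HeJ mouse 40 had the lowest r with its own strain (0.163, next 0.105), and its nearest single mouse was FVB/NJ mouse 146 (0.491, against 0.0533 in its own strain). The Cy3 channel alone, which carried the reference RNA, gave 291 genes over 15 strains, 1284 summed over strains, 79 for the interaction, 1190 for strains on HFD, 7 and 24 for the C57BL and BALB/c pairs and 2 called in 5 strains or more. As a negative control this channel should hold no diet or strain difference, so it was not clean. The cause was not settled, and such signal may also enter the log ratios. The Cy5 channel alone gave 6708 genes over 15 strains. The repeated common RNA correlated best with EtOH mice of C57BL/10J (0.714, next 0.654).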
